A study of Mus musculus with 6 samples.

How the data were processed

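Poly(A)-selected cDNA libraries were made from total RNA of whole mouse corneas (female C57BL/6J, per the labels). There were 6 samples in 3 groups of 2: uninjured corneas (day 0) and corneas taken 5 and 15 days after an alkali burn, a chemical injury that draws blood vessels into the normally avascular cornea. The labels do not say whether the 2 samples of a group came from separate animals, and they give no strandedness.

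The values are FPKM (fragments scaled to transcript length and to the size of the library), as the authors deposited them in a Cuffdiff gene table. The submitters' processing notes name TopHat2 2.1.0, Bowtie2 2.2.6, Cufflinks 2.2.1 and Cuffdiff without a version, and the mm10 build. The table has 28539 loci, of which 23889 carry a gene symbol and 496 name more than 1 gene. Each group has 1 set of columns: an FPKM pooled over its samples, the lower and upper bounds of the authors' interval, and a status. There are 0 columns for single samples, so no spread between replicates could be computed, no test was run, and no p-value is given. Depth is unknown, because FPKM carries no read totals. At FPKM of at least 5, the median half-width of the authors' interval was 54.3% of the FPKM at day 0, 52.9% at day 5 and 52.3% at day 15. The sum of FPKM was dominated by very short loci without a symbol, with 98.1% of the day 0 sum in its 50 most abundant loci.

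The design fixed before the data were examined held 1 rule for pooled columns, which was used. A locus was called apart between 2 groups when the status was OK in both, FPKM was at least 1 in the higher group, the log2 ratio of (FPKM + 1) was at least 1 in size, and the authors' intervals did not overlap. Log2 ratios are on this scale, with a pseudocount of 1, which understates the difference of low genes. Folds are ratios of FPKM without a pseudocount, and none is given against a group listed at 0. The status was OK everywhere except for Krt12 at day 0, where an FPKM of 0 was given with a status of too many fragments, so that no Krt12 ratio to day 0 is reported.

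The named genes were set by a rule of that design: per comparison the 12 largest log2 ratios in each direction among loci apart with FPKM of at least 10 in the higher group, leaving out predicted or unnamed models, ribosomal protein pseudogenes and symbols of microRNA and small nucleolar RNA that start with Mir or Snor, some of which had larger ratios, such as Mir6353 (1007.8 at day 0 and 0 at days 5 and 15); up to 4 members of each list with the largest log2 ratios; and 16 genes given always. There were 36 gene lists, fixed with that design. For each list the median log2 ratio over members with FPKM of at least 1 in at least 1 group was placed among medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A median outside the 2.5 to 97.5 percentiles is called outside the random range, as a description of these libraries and not a p-value. Members on a locus shared with a gene outside the list were left out, a choice made after the data were seen.

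Coordinates are 1-based on mm10. Of 22315 loci with a single symbol in the GENCODE M21 annotation (GRCm38), 98.7% overlapped that gene. A 7-base match to the miR-204-5p seed (AAAGGGA) was searched in the longest annotated 3' UTR of each gene. Random lists for that test were matched in 10 expression bins and 5 bins of UTR length, and the median was also set beside those of other 7mers. Only 34 other 7mers have the same base composition, although 100 had been planned. Loci that merge several genes, and genes with an overlapping gene on the other strand, are uncertain.

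The call rule was tested on simulated groups for day 5 against day 0, over 28539 loci, with values drawn from the authors' intervals. It recovered 22% of 50 loci changed 2.5-fold, 52% of those changed 4-fold, 82% of those changed 8-fold and 74% of those changed 16-fold. The changed loci were drawn only from those with a mean FPKM of at least 5, so that recovery at lower levels was not measured. Among random lists of 20 genes, 3% lay outside the random range, and 92% of lists shifted by 0.6 were found. With no locus changed, 59 were called apart for day 5 against day 0, 64 for day 15 against day 0 and 60 for day 15 against day 5. When the interval width followed the value drawn, these counts were 277, 287 and 227. Alternatives varied the pseudocount, the filter on low values, the fold, the use of intervals, the scaling, loci of 1 symbol summed, the bins, list membership and the site type. Replicate-based alternatives of the design had no columns to run on. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.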

Results

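RNA-seq measured polyadenylated transcripts in whole corneas of uninjured mice (day 0) and of mice 5 and 15 days after an alkali burn, with 2 samples in each of 3 groups. The values are the authors' FPKM, given once per group and pooled over its samples, so that no replicate spread can be shown and no test across animals was possible. Ranges after a value are the authors' interval for that group. A fold against an FPKM near or below 1 is imprecise, as for Il1b, whose interval at day 0 was 0 to 2.19. FPKM reached at least 1 at 14071 loci at day 0, 14067 at day 5 and 13664 at day 15. The number of reads per sample is unknown.

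The comparison of day 5 with day 0 asks how the cornea differs soon after the burn. Some genes of the corneal surface and stroma were far lower at day 5. The medians of the epithelial and keratocyte lists lay inside the random range, though their mean log2 ratios were lower, at -1.57 and -0.73. Chemokines, neutrophil genes, matrix proteases, scar matrix genes and blood vessel markers were higher as lists. Lypd2, a member of the Ly6 family (chromosome 15, 74732252 to 74734313 on mm10), had an FPKM of 13645 (6228 to 21062) at day 0 and 1.37 (0 to 3.76) at day 5. Its neighbour Slurp1, a secreted Ly6-type protein of the corneal surface (chromosome 15, 74721234 to 74728392), stood at 11779.7 (2517 to 21042) and 1.12 (0 to 3.45), with exons that overlap Them6 on the other strand. Ppbp, a chemokine that attracts neutrophils (chromosome 5, 90768409 to 90770942), was at 0.0343 at day 0 and 923 (521 to 1325) at day 5. In all, 533 loci were higher and apart at day 5 and 389 were lower and apart, among 15576 with FPKM of at least 1 in either group.

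Among 22 inflammatory cytokines and chemokines, 16 were higher and apart at day 5 and none was lower and apart, with a median log2 ratio of 3.47, the highest of the 36 lists. Il1b, the interleukin that starts many inflammatory responses, was 98.0-fold higher, at 102 (44.7 to 160.1) against 1.04. Cxcl5 and Cxcl2, both neutrophil attractants, were 50.3-fold and 88.2-fold higher. Cxcl3 was listed at 0 at day 0 and stood at 99.7 (47.1 to 152) at day 5. Csf3, the growth factor of granulocytes, was 152-fold higher. Of 15 neutrophil markers, 8 were higher and apart, with a median log2 ratio of 2.34. S100a8, a calcium-binding protein of neutrophils and stressed epithelia, was 93.5-fold higher, and its partner S100a9 12.4-fold. Ltf, which encodes the iron-binding protein lactoferrin of neutrophils and glands, was 79.3-fold higher and reached 1243 (304 to 2182). Of 21 macrophage markers, 7 were higher and apart, with a median of 1.36, among them the lipopolysaccharide co-receptor Cd14 at 18.2-fold and the lysozyme gene Lyz2 at 5.63-fold.

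Blood vessel markers were higher as a group. Of 23 endothelial markers, 8 were higher and apart and 22 had a higher value at day 5, with a median log2 ratio of 1.47. Pecam1, an adhesion molecule of endothelium, was 6.37-fold higher, and Cdh5, the cadherin of endothelial junctions, 9.53-fold. Aplnr, the apelin receptor, was 18.6-fold higher. Kdr, the main receptor for vascular endothelial growth factor, was at 3.66 at day 0 and 3.47 at day 5, and was not apart. Vegfa itself was at 4.04 (0.655 to 7.42) and 8.43 (2.59 to 14.3), also not apart, as were Flt1 (0.967 and 4.12), Angpt1 (1.59 and 2.85) and Angpt2 (4.85 and 3.63). Among 17 secreted factors that promote vessels, 2 were higher and apart and 1, Fgf1, was lower and apart, with a median of 0.76. Of 14 factors that restrain vessels, 5 were higher and apart, including Col18a1, the precursor of endostatin (15.1-fold), and Thbs1 (4.06-fold), and the list median of 0.74 was close to that of the promoting factors, both above the random range. Lect1, which encodes chondromodulin, and Angptl7 were lower and apart, by 33.1-fold and 17.1-fold. The locus of Angptl7 spans 20.7 times the annotated gene, so that its value is uncertain. Of 5 red blood cell genes, 3 were higher and apart, the globin Hba-a2 by 31.1-fold, in the same samples as the vessel markers.

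Matrix genes were higher. Of 26 fibrosis genes, 11 were higher and apart and none lower and apart, with a median log2 ratio of 1.25. Col3a1, a fibrillar collagen of healing tissue, was 19.9-fold higher, at 1351 (371 to 2331). Postn, a matrix protein of scars, was 12.5-fold higher, and Tnc, the wound matrix protein tenascin, 8.57-fold. Among 16 matrix proteases and related genes, 12 were higher and apart, with a median of 1.75. Mmp13, a collagenase, was 83.2-fold higher, Mmp12 19.0-fold, and Plaur, the urokinase receptor, 48.5-fold. Of 12 cornification and wound-induced genes, 4 were higher and apart and 1, S100a7a (FPKM 22.3 and 1.73), lower and apart, with a median of 0.84. Krt17, a keratin of wounded epithelia, was 39.2-fold higher, Krt16 6.95-fold, and the envelope protein gene Sprr1a 18.6-fold. Sprr1b was listed at 0 at day 0 and had 5.84 (0 to 11.7) at day 5, not apart. The merged locus of Krt6a and Krt6b, keratins of activated epithelium, was at 1812 and 1519. The serpin gene Serpinb2 was 55.3-fold higher, Dmkn, a secreted epidermal protein, 69.6-fold, and the GABA receptor subunit gene Gabrp 250.0-fold. Prl2c2, a prolactin-family hormone, was listed at 0 at day 0 and at 42.2 (12.8 to 71.5) at day 5. The merged locus of the secreted peptides Esp5 and Esp6 was at 3.13 and 998. Of 12 conjunctival and goblet cell markers, 6 were already higher and apart at day 5 and 11 had a higher value, with a median of 1.97.

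Lower at day 5 were some genes of corneal epithelium and keratocytes, and the corneal crystallins as a list. Of 21 corneal epithelial markers, 5 were lower and apart and 1 was higher and apart, and their median of -0.35 lay inside the random range. Their mean was -1.57, with 13 lower and 8 higher values, and was not set against random lists. Aldh3a1, an aldehyde dehydrogenase that forms much of the soluble protein of the mouse cornea, was 30.2-fold lower, from 9149.9 (998 to 17302) to 303 (165 to 441). Dsg1a, a desmosomal cadherin, was 76.9-fold lower and Upk1b, a tetraspanin, 9.62-fold. Spink7 was listed at 0 at days 5 and 15 and at 25.2 (0 to 51.5) at day 0, was not apart, and lies on a locus 46.6 times as long as the annotated gene. Krt12, the main keratin of the corneal epithelium, has no usable day 0 value and is not among the 21. Its day 0 status was too many fragments, so that the listed 0 cannot be read as a low level. Its FPKM was 6.81 (1.34 to 12.3) at day 5 and 9.67 (2.70 to 16.6) at day 15. Pax6, a transcription factor that maintains the cornea, was at 128 at day 0 and 63.6 at day 5 and was not apart, on a locus 16.4 times the span of the annotated gene. Of 20 keratocyte markers, 6 were lower and apart and 2, Thy1 among them (8.97-fold), higher and apart, and the median of -0.03 lay inside the random range. The mean of the keratocyte markers was -0.73. Kera, a keratan sulfate proteoglycan core (chromosome 10, 97607205 to 97613688), was 45.9-fold lower, from 516 (276 to 755) to 11.2. Chst5, a sulfotransferase of keratan sulfate, was 58.3-fold lower and Ptgds, a prostaglandin D synthase, 9.29-fold. Of 9 corneal crystallin genes, 3 were lower and apart, with a median of -1.53. Other large differences were Mgarp (124-fold lower), the neuropeptide gene Npy (143-fold), the protease inhibitor gene A2m (106-fold), the carbonic anhydrase gene Car3 (94.8-fold), Ppp1r3c, a regulator of glycogen synthesis (327-fold), Rasgrf1 (167-fold) and Erich5 (50.6-fold). The merged locus of Cd27 and a microRNA was 320.4-fold lower, and its assignment is uncertain.

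Tissue next to the cornea differed in the same samples. Of 15 lens markers, 8 were lower and apart at day 5, with a median of -2.28, and Cryaa, a lens crystallin, was at 158 and 10.6. Of 10 iris and pigment markers, 2 were lower and apart, with a median of -1.37, and of 13 photoreceptor markers 1, with a median of -0.52. None of 14 skeletal muscle markers was apart, with a median of -0.62. The medians of these 4 lists lay below the random range, that of the photoreceptor list with 20 expression bins and not with 10. Among reference genes none of 14 was apart, with a median of 0.35 just inside the random range. A simulation with every locus unchanged called 59 loci apart, or 277 when the interval width followed the value drawn, and 922 were called here. Without the interval rule the counts are 1687 higher and 1722 lower, so that the balance turns.

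**Figure D1:**
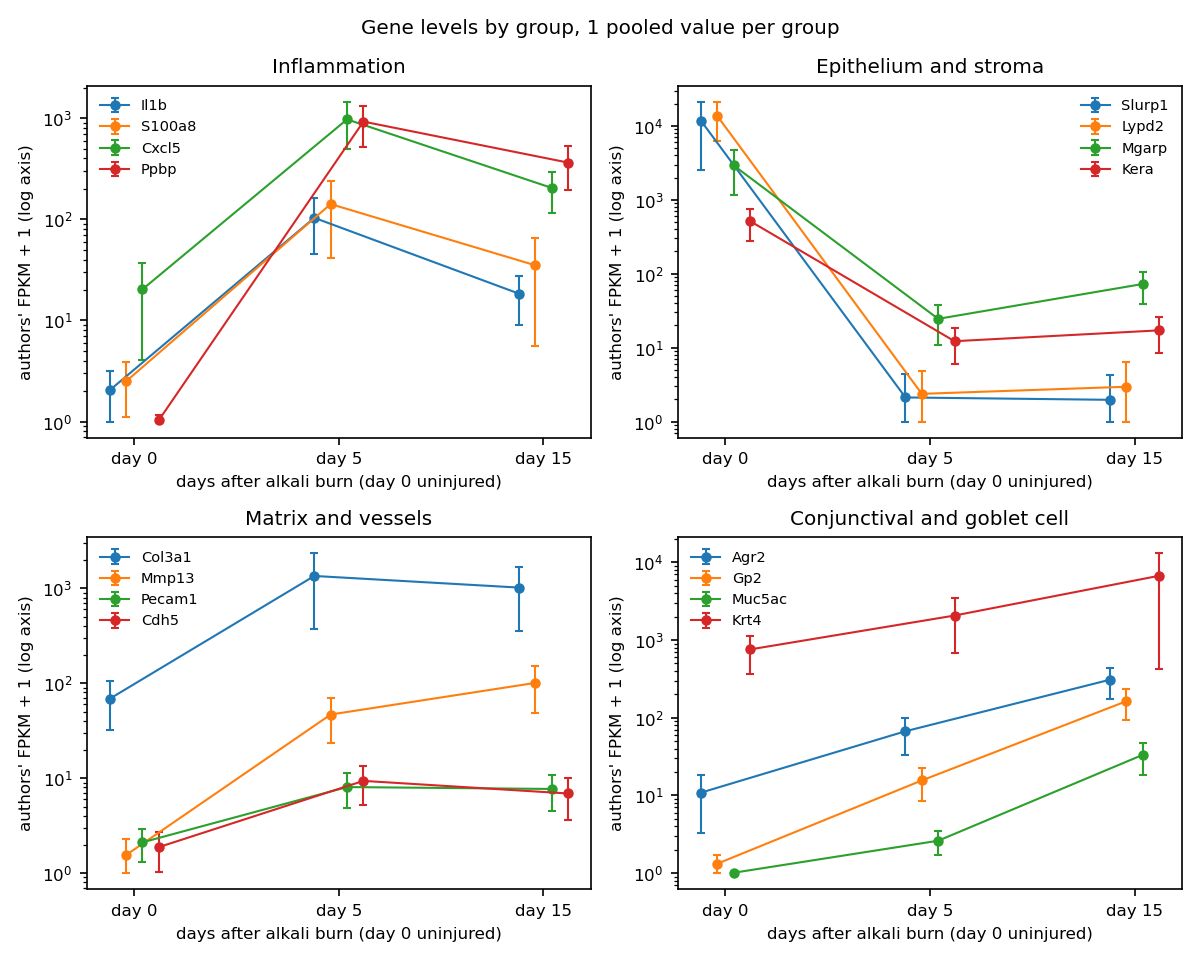
The authors' FPKM + 1 of 16 genes at days 0, 5 and 15, on a log axis, with 1 point per group, pooled over 2 samples, and bars for the authors' interval. Lypd2 stands at 13645 at day 0 and 1.37 at day 5, while Ppbp stands at 0.0343 and 923 (FPKM before 1 is added).

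The comparison of day 15 with day 0 asks what remains apart at the later time. Most of what stood apart at day 5 was still apart in the same direction, and genes of conjunctival and goblet cells were higher, as they already were at day 5. Of 12 conjunctival and goblet cell markers, 9 were higher and apart, with a median log2 ratio of 2.69. Muc5ac, the gel-forming mucin of goblet cells, stood at 32.3 (17.6 to 47.0) against 0.0104 at day 0, and Agr2, an endoplasmic reticulum protein needed for mucin production, was 31.3-fold higher. Tff1, a trefoil peptide secreted with mucins, was listed at 0 at day 0 and had 96.2 (38.3 to 154) at day 15. Gp2, a membrane glycoprotein, was 505-fold higher. There were 442 loci higher and apart and 275 lower and apart, among 15186.

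Krt4, a keratin of conjunctiva, had a value of 6734 (429 to 13038) against 757 (369 to 1145) and was not apart. Krt8 and Krt18, keratins of simple epithelia, were 12.8-fold and 4.15-fold higher. Serpinb3a, a protease inhibitor, was 41.4-fold higher and reached 2798 (942 to 4655), Tspan8, a tetraspanin, was 69.9-fold higher, and Gabrp 291-fold. Spink12 was listed at 0 at day 0 and had 59.0 (27.7 to 90.3). Aqp4, a water channel, was 60.3-fold higher and the Esp5 and Esp6 locus 998-fold. Ppbp was at 363 (193 to 533), Ltf was 48.5-fold higher and Serpinb2 65.1-fold. S100a8 was still 22.7-fold higher and Il1b 16.7-fold, while S100a9, at 63.1 (21.8 to 104), was not apart. Of 21 macrophage markers, 13 were higher and apart, with a median of 1.99, including Lyz2, which stood at 685 (381 to 988). The arginase gene Arg1, also on that list, was 6.98-fold higher, at 654 against 93.6. Its day 0 level was far above that of the macrophage marker Emr1 (1.53), and which cells express it was not tested. Of 10 antigen presentation genes, 3 were higher and apart, among them H2-Aa, a chain of MHC class II (3.96-fold).

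Vessel and matrix genes were also higher at day 15. Of 23 endothelial markers, 9 were higher and apart and all 23 had a higher value, with a median of 1.36. Pecam1 was 6.04-fold higher and Cdh5 6.72-fold, while Kdr (3.88), Vegfa (4.76), Flt1 (3.96), Angpt1 (3.86) and Angpt2 (3.32) were not apart from day 0. The factors promoting vessels had a median of 0.19 and those restraining them 0.23, both inside the random range. Of 26 fibrosis genes, 8 were higher and apart, with Col3a1 15.0-fold, Postn 12.2-fold and Tnc 9.07-fold higher. Of 16 matrix proteases, 6 were higher and apart, and Mmp13 was 181-fold higher. Krt17, higher and apart, was at 359.9 (209 to 511), and Sprr1b stood at 0.251.

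Several corneal genes were still lower at day 15. Slurp1 stood at 0.971 (0 to 3.30), Lypd2 at 1.96 and Kera at 16.2, 31.9-fold lower than at day 0. Mgarp was 40.8-fold lower, Npy 53.1-fold, A2m 41.9-fold, Car3 146-fold, Ppp1r3c 308-fold and Rasgrf1 61.0-fold. Slc4a11, a transporter of the corneal endothelium, was 54.0-fold lower and Fam83a 66.6-fold. Aldh3a1 was at 866 (437 to 1294) and Psca, a Ly6-family gene next to Slurp1, at 4903 (2003 to 7803) against 10585 at day 0, and neither was apart. Of 21 corneal epithelial markers, 2 were lower and 1 higher and apart, with a median of -0.04, and of 20 keratocyte markers 4 were lower and 2 higher and apart, with a median of -0.24, both inside the random range. The means of these 2 lists were -1.08 and -0.54. Muscle markers stood out among neighbouring tissues: 7 of 14 were lower and apart, with a median of -2.22, and Myl1, a myosin light chain, was at 430.0 and 55.8. The lens median was -0.65, with no member apart, and the photoreceptor median 0.68. Of 14 reference genes 1, B2m, was higher and apart (3.06-fold, on a locus 12.2 times the span of the annotated gene), with a median of 0.31 inside the random range. The simulation with every locus unchanged called 64 or 287 loci apart, against 717 here. Without the interval rule the counts are 1270 and 1432, and the balance turns.

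**Figure D2:**
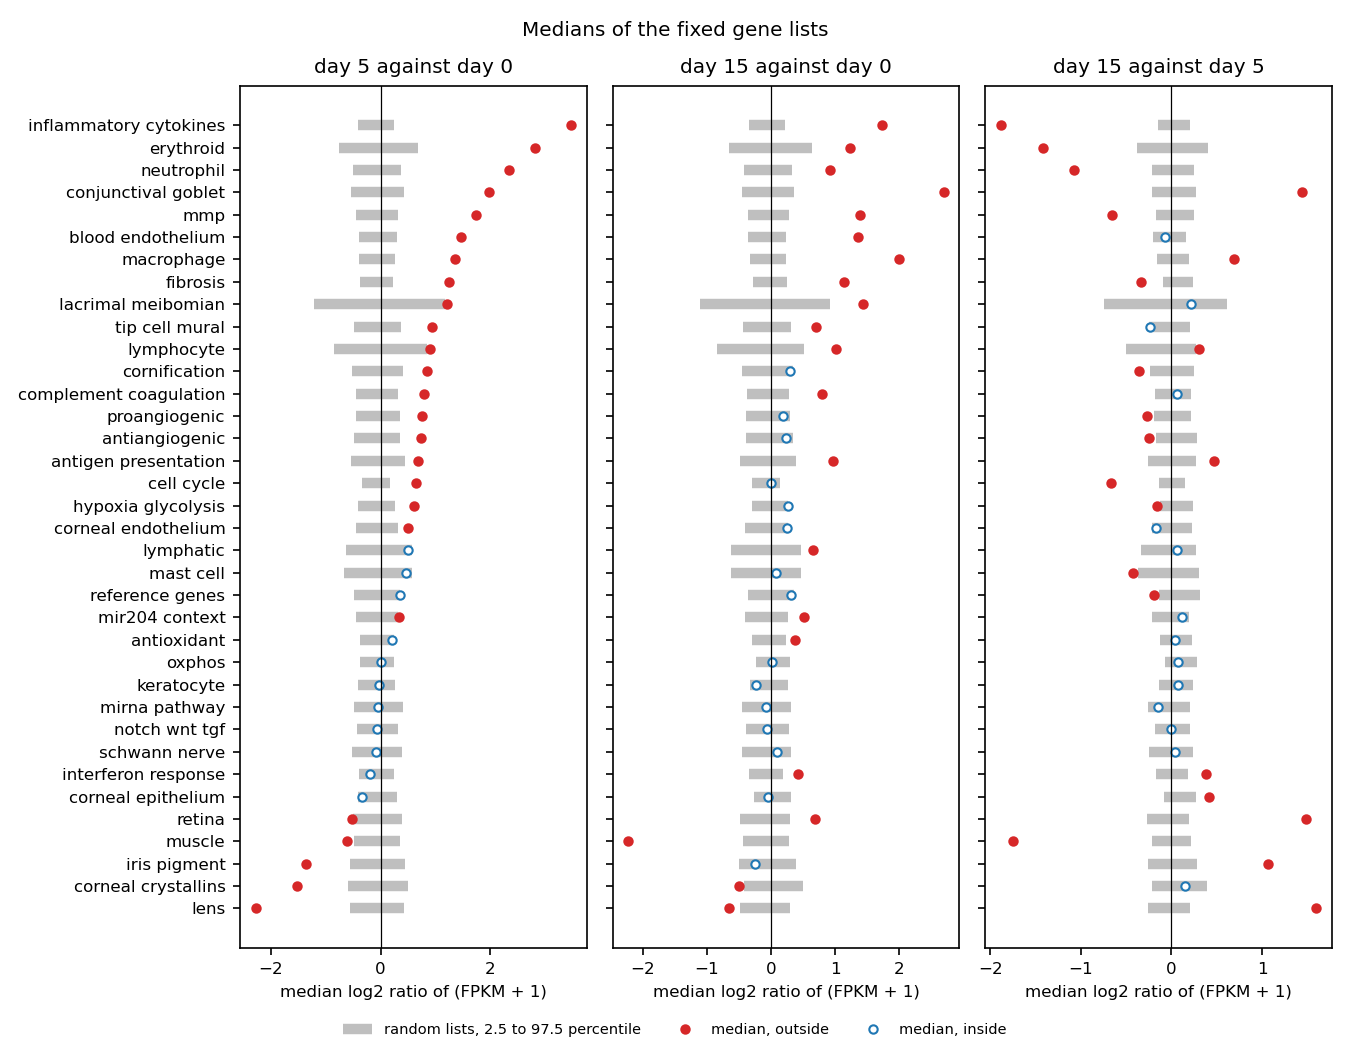
Median log2 ratio of (FPKM + 1) of each of the 36 gene lists (horizontal axis) in the 3 comparisons. The grey bars span the random range and filled points lie outside them: 25 lists at day 5 and 21 at day 15 against day 0, and 22 at day 15 against day 5.

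The comparison of day 15 with day 5 follows the injured cornea over time. Goblet cell genes were higher and chemokines lower at day 15. Muc5ac stood at 1.61 at day 5 and 32.3 at day 15. Gp2 was 11.1-fold higher at day 15, Tff1 9.17-fold and Spink12 11.8-fold, as were Ly6d, a Ly6 protein of epithelia (11.2-fold), Reg3g, a lectin that kills bacteria (14.9-fold), and Psca (6.48-fold). Of 22 cytokines and chemokines, 10 were lower and apart, with a median log2 ratio of -1.88. There were 58 loci higher and apart and 57 lower and apart, among 14683.

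Among the cytokines, Il24 was 35.0-fold lower at day 15, Csf3 14.3-fold, Cxcl3 7.69-fold, Cxcl1 7.04-fold and Il1b 5.88-fold. Cxcl2 was at 135 at day 5 and 12.3 (3.38 to 21.3) at day 15. Hdc, which makes histamine, was 13.1-fold lower, Irg1, an enzyme of activated macrophages, 17.5-fold, and the merged Trem1 and Trem3 locus 8.75-fold. Prl2c2 was 69.5-fold lower, Prl2c3 52.6-fold and Ang2, a ribonuclease of the angiogenin family, 108-fold. The merged Snhg1 locus, which holds small nucleolar RNA, was 8.52-fold lower. Rnu12, a small nuclear RNA that a poly(A) library captures poorly, was 11.2-fold higher. Of 15 neutrophil markers, 1 was lower and apart, with a median of -1.08. Of 21 macrophage markers, 1, Cd14, was lower and apart, while the median was 0.69. Of 23 endothelial markers, 1, Erg, a transcription factor, was lower and apart, and the median of -0.07 lay inside the random range. None of 30 cell cycle genes was apart in any comparison, but their median was 0.65 at day 5 against day 0, 0.00 at day 15 against day 0 and -0.67 at day 15 against day 5, and 29 of the 30 had a lower value at day 15 than at day 5. Of 12 goblet cell markers, 4 were higher and apart.

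Lens genes were among the loci higher at day 15 than at day 5. Of 15 lens markers, 5 were higher and apart, with a median of 1.60, including Cryaa (6.89-fold), Cryba1 (8.50-fold), Crybb2 (7.52-fold) and Crybb3 (7.01-fold). The pigment list had a median of 1.07 and the photoreceptor list 1.48, whereas muscle had -1.75 with 7 of 14 lower and apart. None of 14 reference genes was apart, but their median of -0.19 lay below the random range. Simulation with every locus unchanged called 60 loci apart, or 227 when the interval width followed the value drawn, and 115 were called here. The simulation draws noise at the full width of the authors' intervals. At FPKM of at least 5, the robust spread of the observed differences was only 0.57 of what those intervals imply. The simulated counts may therefore overstate the noise, and they do not decide how many of the 115 loci are noise. Without the interval rule the counts are 384 and 492.

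**Figure D3:**
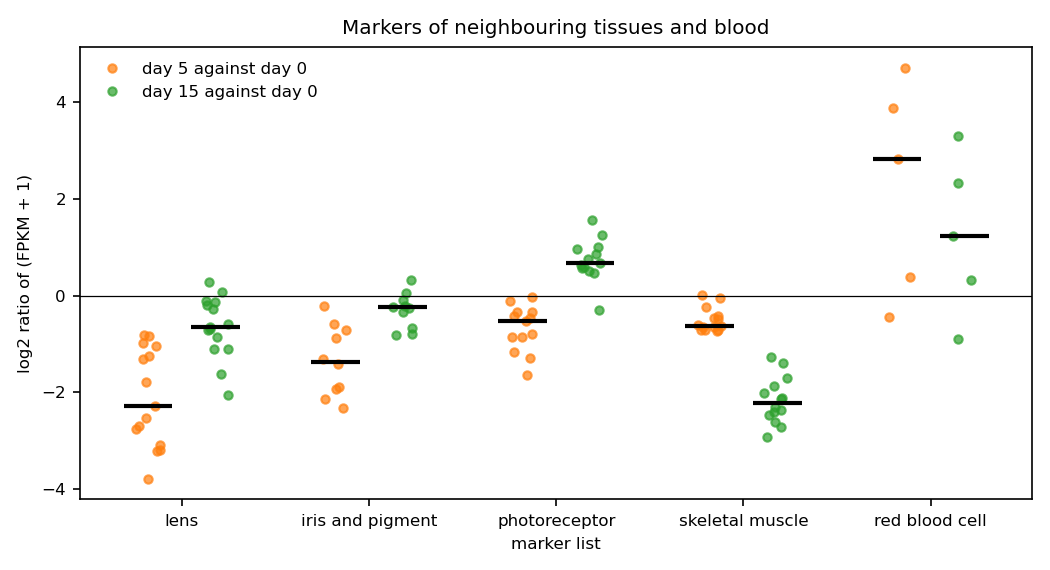
Log2 ratios of (FPKM + 1) of markers of tissues next to the cornea and of red blood cells at days 5 and 15 against day 0, with 1 point per gene and a black bar at each median. The lens median is -2.28 at day 5 and -0.65 at day 15 against day 0, while the muscle median is -0.62 and -2.22.

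How far genes were back near the day 0 level at day 15, which the submitters' protocol describes as a regression stage, was examined next. Of the 533 loci higher and apart at day 5, 97 (18.2%, exact Clopper-Pearson interval 15.0 to 21.7%) were within 2-fold of day 0 at day 15, and 429 (80.5%) were closer to day 0 than at day 5. The 18.2% depends on the scale and window, at 5.19% with a pseudocount of 0.1 and 6.00% within 1.5-fold. Of the 389 lower and apart, 58 (14.9%, interval 11.5 to 18.8%) were within 2-fold, or 4.63% within 1.5-fold, and 318 (81.7%) were closer. Loci called by noise alone in the simulation came within 2-fold more often, at 48.3% for higher and 68.4% for lower loci, and closer in 96.6% and 91.5%. The intervals treat loci as independent, which genes are not. Among the genes named here, Prl2c2 and Il24 stood at 0.607 and 0.683 at day 15, while Lypd2 and Kera remained far below day 0.

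The differences at days 5 and 15 were shared. Of 14862 loci that could be compared, 323 were higher and apart at both times and 225 lower and apart at both, and none had opposite directions. Simulated unchanged groups that share day 0 gave 1.58 and 4.21 on average, and none in opposite directions either. Their interval width followed the simulated level, the setting with fewer calls, and the other setting was not run for the overlap. The log2 ratios at the 2 times correlated across genes at r = 0.878, with 0.558 in simulated unchanged groups, because both use the same day 0 value. Across genes, which are not independent replicates, 83.2% had the same sign, against 68.7% in the simulation.

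**Figure D4:**
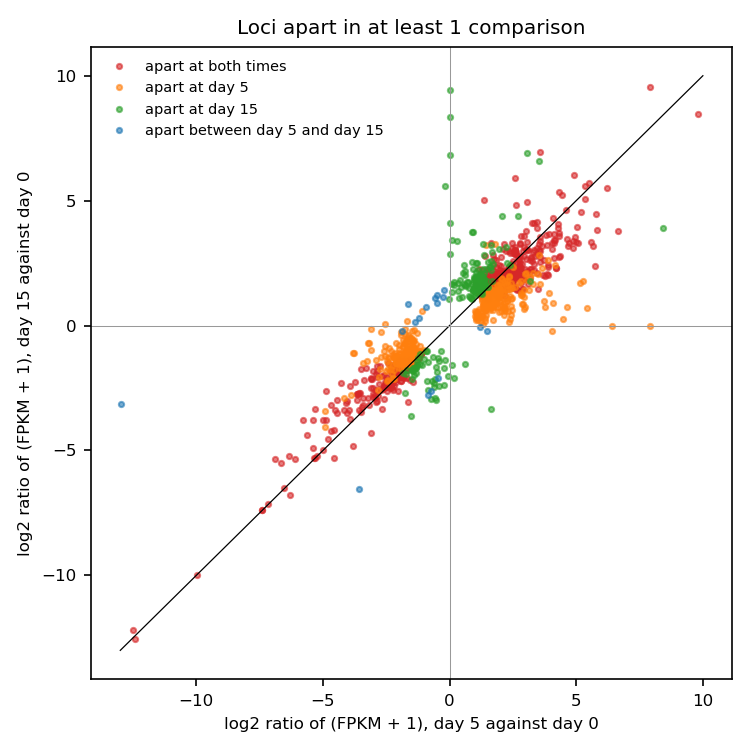
Log2 ratio of (FPKM + 1) against day 0 at day 5 (horizontal axis) and day 15 (vertical axis), with 1 point per locus called apart in at least 1 comparison and the line of equal ratios. The 323 loci higher and apart at both times lie at upper right and the 225 lower and apart at both at lower left.

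The title of the series names miR-204, a microRNA that lies in an intron of Trpm3, a cation channel gene. Trpm3 (chromosome 19, 22139117 to 22990470) stood at 129 (11.3 to 247) at day 0, 3.25 (0 to 7.79) at day 5 and 6.76 (0 to 14.0) at day 15, and was apart at day 5 but not at day 15. Genes with a match to the miR-204-5p seed in the 3' UTR, 1953 of 12034, had a median log2 ratio 0.03 above that of genes without a site at day 5 and 0.03 at day 15. These medians stood at the 73.9 and 85.1 percentiles of matched random lists, and at 70.7 for day 15 against day 5, all inside the random range. Of 34 other 7mers of the same base composition, 23 gave a lower difference at day 5, 28 at day 15 and 16 for day 15 against day 5. A separate list of 17 measured genes, the host gene and genes described elsewhere as targets, had 1 member higher and apart and 3 lower and apart at day 5, with a median of 0.34 that lay outside the random range, but not with a pseudocount of 0.1. Sox4, a transcription factor, was 9.26-fold higher, while the neurotrophin receptor gene Ntrk2 stood at 36.9 and 2.31 and Ezr, a linker of membrane and actin, was 3.48-fold lower. At day 15 Sox4 and Sox11 were higher and apart and Ntrk2 lower and apart, with a list median of 0.51, also outside the random range. The microRNA itself was not analysed here.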

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

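No test was run in this part, and a look at loci without a symbol was not in the design fixed before the data were examined. The comparisons of the report name genes with a symbol, so that loci without one were looked at separately. Of these, 16 were higher and apart at day 5 against the uninjured corneas, and 48 were lower and apart. The most abundant of the 16 lies on chromosome 17, 34996697 to 35000331 on mm10, with an FPKM of 21.3 at day 0, 391 at day 5 and 285 at day 15. Next came a locus on chromosome 7, 19933554 to 19933973, at 0.141, 13.4 and 4.64, and one on chromosome 10, 83988148 to 83988336, at 1.98, 7.02 and 26.6. What these loci encode was not examined.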

How the results depend on the processing

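The restrictions to loci with a symbol or of at least 300 bp, the list members kept on shared loci, and the pseudocount of 0.1 without a filter were chosen after seeing the data. No paired analysis was possible because the table gives 1 pooled column per group, and for the same reason the replicate block, leaving out each replicate, the limma-trend fit and the count-based fits were not run. With a 4-fold minimum, 308 loci were higher and 199 lower at day 5 against day 0, 232 and 147 at day 15 against day 0, and 27 and 26 at day 15 against day 5. Without the interval rule these were 1687 and 1722, 1270 and 1432, and 384 and 492. Both follow from the stricter or looser call itself. Loci higher at both times were 163 with the 4-fold minimum and 920 without intervals, and those lower at both 118 and 1082. Within 1.5-fold of day 0, 6.00% of the loci higher at day 5 and 4.63% of those lower had come back by day 15, by a narrower window, and with a pseudocount of 0.1 the share of higher loci was 5.19%, since that scale spreads low values. The counts per direction kept within 1.5 times of the reported ones with both pseudocounts, the higher filter, the 1.5-fold minimum, both rescalings, summed symbols and the 3 choices added later that bear on them. Leaving out the filter at a pseudocount of 1 moves nothing by arithmetic, since a 2-fold difference on that scale already needs an FPKM above 1, and says nothing about stability. Rescaling to the sum without the 50 most abundant loci moves day 5 by 0.17 and day 15 by 0.07 on the log2 scale. The balance of calls turned without the interval rule, from 57.8% to 49.5% higher at day 5 and from 61.6% to 47.0% at day 15 against day 0, and the cause was not tested. For day 15 against day 5 it went from 50.4% to 40.9% higher with that rescaled sum, at 47 and 68 loci. No list median outside the random range and no named gene that was called reversed its sign. Of 108 list medians, 104 kept their side of the random range with 10 bins, 99 with all members, 105 after rescaling by the median ratio and 101 with a pseudocount of 0.1. That of the miR-204 list at day 5 came inside the range with a pseudocount of 0.1, at 0.36. Of 829 ratios of named genes 276 were called, of which 59 were lost with the 4-fold minimum, 18 with a pseudocount of 5, 8 with the higher filter, 5 after rescaling by the median ratio and 10 with the rescaled sum, and the last 2 added 7 and 11. Depth is unknown, and the self-test at the authors' interval widths found 22% of loci changed 2.5-fold, all of them with a mean FPKM of at least 5.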

Other observations

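The list medians in this part were planned, and of the other tests all but the median of the general epithelial genes were chosen after the result was seen, and how that median is read was narrowed afterwards. Several gene groups have no place in the account above. None of 22 interferon-stimulated genes was apart, with a median log2 ratio of -0.19 at day 5 and 0.42 at day 15 against day 0, the latter outside the random range. Of 16 complement and coagulation genes, 3 were higher and apart at day 5 and 2 at day 15, with a median of 0.79 at both times, among them C3ar1, a complement receptor (4.45-fold and 6.74-fold), and F13a1, a clotting transglutaminase (5.33-fold and 5.68-fold). Of 20 hypoxia and glycolysis genes, 3 were higher and 1 lower and apart at day 5, with a median of 0.60, including the hexokinase gene Hk2 (4.66-fold) and Bnip3, a mitochondrial protein of the hypoxia response (3.79-fold), while Egln3, an oxygen sensor, was 6.11-fold lower. Of 22 antioxidant genes, 3 were higher and 1 lower and apart at day 5, with a median of 0.20 inside the random range, and Hmox1, the inducible heme oxygenase, was 11.3-fold higher and Gpx3, a secreted peroxidase, 5.05-fold. None of 24 respiratory chain genes and none of 12 microRNA pathway genes was apart, with medians of 0.00 and -0.05 at day 5. Of 14 corneal endothelial markers, 2 were higher and 2 lower and apart at day 5, with a median of 0.50 above the random range. Slc16a3, a lactate transporter, was 11.6-fold and Col8a1, a collagen of Descemet's membrane, 3.82-fold higher, and Slc4a11 was 18.0-fold and Col4a3, a basement membrane collagen, 22.6-fold lower.

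Of 14 tip cell and pericyte markers, 2 were higher and apart at day 5, Esm1, a secreted protein of sprouting endothelium (7.50-fold), and Mcam, an adhesion molecule of vessels (5.40-fold), with a median of 0.94. Of 9 lymphatic markers, 1, Nrp2, a receptor of lymphatic growth factors, was higher and apart at day 5 (3.92-fold). Their median was 0.49 at day 5, inside the random range, and 0.65 at day 15, above it. At day 15 all 9 had a higher value than at day 0 and none was apart. Of 24 lymphocyte markers only 7 were measured, and none of these was apart. Their medians of 0.90 at day 5 and 1.01 at day 15 against day 0 both lay above the random range. Of 7 mast cell genes, only Hdc was higher and apart at day 5 (80.8-fold) and 6 were not apart, with a median of 0.46 inside the random range. Of 12 Schwann cell genes, S100b was 4.74-fold lower at day 5. Of 19 readouts of Notch, Wnt and TGF-beta signalling, 3 were higher and 1 lower and apart at day 5, and the median was -0.07. The lacrimal and meibomian list had only 2 measured members and its medians were unstable. Xist was at 32.3, 26.0 and 22.1 and 4 genes of the Y chromosome were at 0 in all groups.

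Some corneal epithelial and keratocyte genes were far lower after injury, while the medians of both lists lay inside the random range. Less epithelium in the injured samples, or dilution by infiltrating cells, cannot be told apart from lower expression for the list of corneal epithelial markers: the bound set beforehand against it was met, with 20 general epithelial genes at a median log2 ratio of -0.32 at day 5 and the 5 lower markers at -1.40 or below, but those markers were picked by the call, and the whole list had -0.35. Slurp1 and Dsg1a, picked after their low values were seen, had ratios of -9.14 and -4.27 at the nearest bounds of the authors' intervals. The lowest general epithelial gene had -1.53. An equal loss of all epithelium would not by itself give the values of these 2 genes, but they were picked for being low and decide nothing for the other markers. Failed estimates, as of Krt12 at day 0, are argued against only for the 11 members of both lists that were lower and apart at day 5 or 15. Of these, 0% were listed at 0, as 29 other loci lower and apart were, and no locus had a failed status at those times. The call itself requires a status of OK. Spink7, listed at 0 at both times but not apart, is not among the 11, and for it a failed estimate stays open. Replacement of corneal by other epithelium, loss of keratocytes and an effect of the injury on these genes were not tested and stay open.

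Trpm3, the host gene of miR-204, had lower values after injury, apart at day 5 only. Less lens, iris or retina tissue cannot be told apart from lower expression: the lowest of 36 markers stood at -3.78 at day 5 (Cryaa) and -2.05 at day 15 (Crygb) and Trpm3 at -4.94 and -4.07, but at the nearest bounds of its intervals Trpm3 had -0.48 and 0.28. An imprecise day 0 estimate cannot be told apart at day 5 either, since -0.48 is less than a 2-fold difference, and could account for the difference at day 15, where 0.28 means that the intervals overlap. An effect of the injury stays open. The locus carrying the symbol Mir204, looked up after these values were seen, spans the Trpm3 region and had 8.11 (0 to 18.3) at day 0, 0.305 at day 5 and 0.720 at day 15, which a poly(A) library does not make a measure of the microRNA.

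Conjunctival and goblet cell genes were higher at day 15, and at day 5 with a median log2 ratio of 1.97, when muscle stood at -0.62. A wider excision with more muscle is argued against at day 15, since all 14 skeletal muscle markers lay below day 0, with a median of -2.22. Other neighbouring tissue stays open, as photoreceptor markers had a median of 0.68 with 12 of 13 higher, but lens markers -0.65 with 13 of 15 lower and pigment markers -0.25 with 8 of 10 lower. More conjunctival epithelium in the samples cannot be told apart from a difference within the cornea. The 11 markers with a day 0 value ranged over 4.08 on the log2 scale, from Clca1 at 0.96 to Muc5ac at 5.04. The pseudocount limits the ratio of genes with a low FPKM, so that this range does not show whether the markers rose by different factors. Where their day 0 signal comes from is also not known. Growth of conjunctival cells onto the burned cornea may be the source, and was not tested.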
